A study of Mus musculus with 9 samples.

How the data were processed

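RNA was measured in GFP-positive tumour cells sorted from mouse lung tumour spheroids, in 9 libraries that fall into 3 groups of 3: tumour cells (KP-GFP) grown alone, with lung tissue-resident macrophages (TRMs, the alveolar macrophages of the lung), or with bone-marrow monocytes. Per the labels' protocols, each spheroid began with 2500 tumour cells, alone or with 5000 added TRMs or monocytes, and was kept for 7 days. For each condition 32 spheroids were pooled and dissociated for 20 min at 37 °C before GFP-positive cells were sorted. RNA came from 20000 to 170000 sorted cells; the number per sample is not given. SMART-Seq v4 cDNA was made from 1 ng of RNA and sequenced on an Illumina NextSeq instrument. The kit is not stated to mark strand, so reads of a gene and of a partner on the opposite strand cannot be told apart. Groups and replicate numbers were taken from the sample labels.

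The submitters' processing notes name STAR 2.5, edgeR and the mm10 genome build. The counting tool and the gene annotation are not given in the sources used here. The deposited table of values holds a normalised signal for each of 12339 genes, not whole counts. Each deposited value is a whole number of reads plus 0.5 read, divided by a scaled library size and expressed as CPM. All 111051 values (100%) gave whole reads within a tolerance of 1e-06 of a read, with a largest deviation of 2.2e-09. The scaled library sizes equalled the library totals multiplied by edgeR's TMM factors, up to a factor of 1.00095 to 1.00096 shared by the libraries. The lowest total of a gene over all libraries was 91 reads, so the table holds no gene with few reads. The authors' deposited tables of their own comparisons hold log2 fold changes and a mean log2 level, per the file headers. They also hold a likelihood ratio score per gene, per the file headers. Their p-values and false discovery rates are the authors' and were used only to compare calls.

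Computation used R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15. A filter on the recovered reads (edgeR's filterByExpr, minimum count 10 and minimum total 15) removed 13 genes and left 12326. Log2 values were tested with limma, with a variance prior that follows mean expression, over all 9 libraries with group means as the sole terms and 6 residual degrees of freedom. The 3 contrasts were TRM co-culture against alone, monocyte co-culture against alone, and TRM co-culture against monocyte co-culture. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The planned test was edgeR's quasi-likelihood test on counts, with limma's camera on log CPM for gene lists. The values turned out to be scaled and to carry 0.5 read, so limma on log2 values took its place, camera was run on the same values, and edgeR on the recovered reads became an alternative. Fold changes are ratios on this log2 scale. The added 0.5 read makes them understate changes of low genes. Standard errors come from limma.

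The 31 gene lists covered programmes of the tumour cells, signs of RNA quality and markers of other cell types that a GFP gate could let through. The 28 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over 84 tests, and again with a correlation estimated for each list and with fry. Groups, contrasts, gene lists, the rule for naming genes and most alternatives were set before the data were examined. The rule took, for each contrast, called genes whose groups did not overlap and whose mean was at least 5 in the higher group: the 5 largest folds and the 5 smallest p-values in each direction (3 and 3 between the co-cultures). It added up to 4 members of each list by smallest p. Sex-linked and predicted genes were passed over, genes of other cell types were kept under their list, and genes such as Trp53 and Ptprc were added in advance. The rule named 241 genes, of which some are not reported here.

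Gene positions come from the GENCODE M21 annotation of GRCm38 (mm10). Of the gene names in the table, 12255 matched 1 annotated gene, 62 matched none and 22 matched 2. GC content and transcript length were found for 99.5% of genes. Among the 241 named genes, 75 share exon sequence with another annotated gene.

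Replicates were compared before averaging. The chi-square of recovered reads per gene between replicates of a group lay between 21.5 and 91.5, far above sampling noise, and correlations of log2 values across genes lay between 0.908 and 0.974, so no library was treated as a copy of another. The full procedure was tested on simulated counts drawn from the means and library sizes of the real data, with 100 genes changed 2-fold and 100 changed 4-fold among 12326. For TRM co-culture against alone, 62% and 86% of those genes were called, with 10 unchanged genes called. For monocyte co-culture against alone the shares were 56% and 85%, with 1 unchanged gene called. Between the co-cultures they were 53% and 84%, with 8 unchanged genes called. Because both co-cultures were compared with the same control libraries, 50 simulations of unchanged groups against those controls gave the correlation and covariance that shared controls alone produce.

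Alternatives were RLE and upper-quartile factors, DESeq2, limma-voom, other filters (no filter, or at least 1 CPM in 3 libraries), fits of only the groups compared, the replicate number as a block, robust variances, removal of mitochondrial and myeloid marker genes, a 2-fold minimum, and each library left out in turn. Chosen after seeing the data were edgeR's quasi-likelihood test on the recovered reads, log2(value + 1), scaling by library totals, and removal of each library's trend with GC content and transcript length (splines with 5 degrees of freedom). Intervals of read ratios are 95% intervals and cover counting error only.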

Results

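KP-GFP cells are mouse lung tumour cells that carry GFP. The cells were grown as spheroids alone, with TRMs or with bone-marrow monocytes, and GFP-positive cells were sorted for RNA sequencing. The question was how tumour cells differed after growth with each added cell population. Each group has 3 libraries. Recovered reads were 21341370, 21386212 and 32771448 for replicates 1 to 3 of the tumour cells alone, 16001895, 17879430 and 25240220 for the TRM co-culture, and 18381707, 24037053 and 23931770 for the monocyte co-culture. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. Gene values are CPM (reads scaled to the TMM library size), given as mean ± SD over n = 3 libraries per group.

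The first principal component held 35.9% of the variance, with the tumour cells alone between -80.8 and -44.4 and the co-culture libraries between -12.0 and 51.0. On the second component (20.9%), monocyte co-culture replicate 3 stood at -75.9, and the other libraries lay between -32.9 and 50.3. Mitochondrial transcripts took 0.667%, 0.646% and 0.523% of reads in tumour cells alone, 0.622%, 0.316% and 0.447% with TRMs, and 0.288%, 0.481% and 0.58% with monocytes. Trp53, which encodes the tumour suppressor p53, was at 6.44 ± 1.67 alone, 3.44 ± 0.633 with TRMs and 2.85 ± 1.64 with monocytes. Its fall with monocytes (log2 -1.32, limma adjusted p = 0.0407) was lost without alone replicate 1 (0.069), 2 (0.125) or 3 (0.0853), TRM replicate 2 (0.0588) or 3 (0.0547), or monocyte replicate 1 (0.0754) or 2 (0.151), in edgeR (0.069) and in a fit of only the groups compared (0.0695). Ptprc, which encodes the leukocyte antigen CD45, was at 1.93 ± 1.35, 1.95 ± 2.19 and 0.241 ± 0.287. Its lower value with monocytes (log2 -3.82, limma adjusted p = 0.0361) was lost without alone replicate 1 (0.138), 2 (0.0712) or 3 (0.0612), TRM replicate 3 (0.0521), or monocyte replicate 1 (0.0617) or 3 (0.0801). It was also lost in limma-voom (0.106), in edgeR (0.0778), with log2(value + 1) (0.0785), in a fit of only the groups compared (0.0675) and with the GC and length trend removed (0.0534).

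The first comparison asked how tumour cells differed after growth with TRMs. Slc16a3, which encodes a lactate exporter, was at 3.91 ± 0.411 (SD, n = 3) alone and 80.8 ± 26.6 (SD, n = 3) with TRMs, a 20.1-fold rise (log2 4.33, SE 0.27, limma adjusted p = 7.5e-07). Ldha, the lactate dehydrogenase subunit that makes lactate from pyruvate, rose 5.2-fold, from 499 ± 71.8 to 2585 ± 202 (SD, n = 3; limma adjusted p = 7.69e-07). Egln1, an oxygen-sensing prolyl hydroxylase, rose 4.88-fold, from 93.4 ± 8.12 to 455 ± 32.5 (SD, n = 3; limma adjusted p = 7.16e-07). Gstm1, which encodes a glutathione transferase, fell from 579 ± 53.3 to 101 ± 25.2 (SD, n = 3; 5.86-fold lower, log2 -2.55, limma adjusted p = 3.11e-06).

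In the glycolysis list 17 of 19 tested genes rose with TRMs and 2 did not pass, and 17 rose adjusted over the list alone (camera adjusted p = 3.18e-24; adjusted p = 0.0817 with an estimated correlation). Besides Slc16a3 and Ldha, the phosphofructokinases Pfkp (15.7 ± 1.71 to 208 ± 49.96, 13.1-fold, limma adjusted p = 1.41e-07) and Pfkl (5.19-fold) and the mutase Pgam1 (4.17-fold) rose. In the hypoxia list 21 of 27 rose, 1 fell and 5 did not pass, with 21 and 1 adjusted over the list alone (camera adjusted p = 1e-16; adjusted p = 0.0634 with an estimated correlation). Bnip3, a mitophagy receptor, rose 11.2-fold, Egln3 7.63-fold and the adenylate kinase Ak4 5.55-fold. In the same libraries Mrc1, the mannose receptor of macrophages, rose 6.23-fold to 32.9 ± 9.27, and F13a1, a monocyte gene, rose 14.0-fold to 13.4 ± 3.82.

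**Figure D1:**
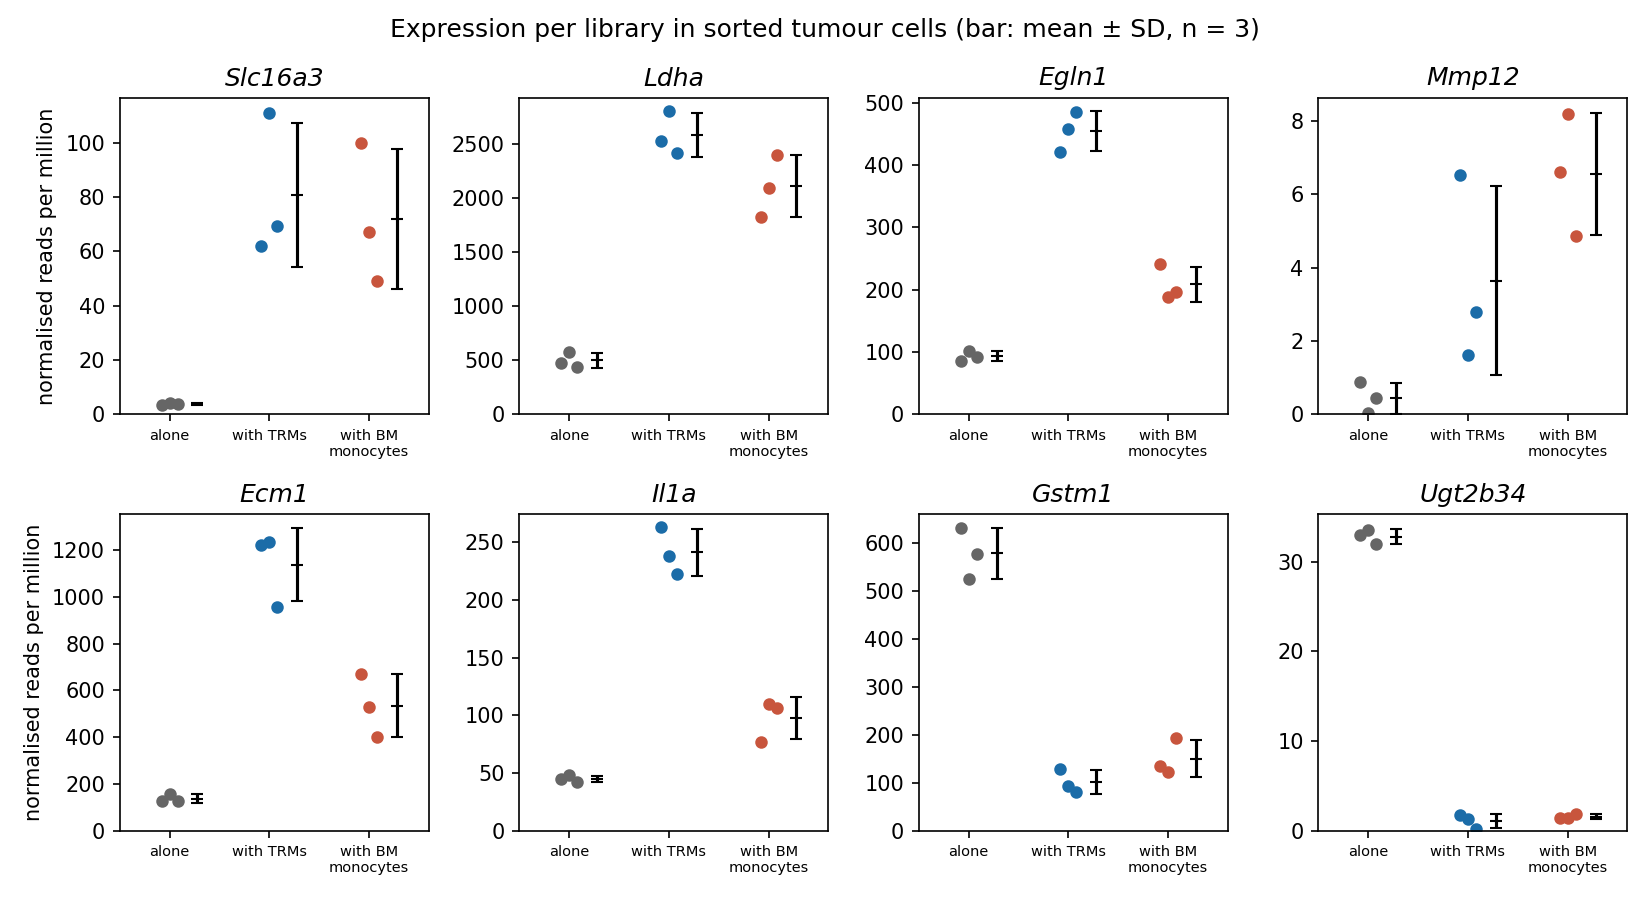
CPM of 8 named genes in each library, on linear axes from 0, for tumour cells alone, with TRMs and with bone-marrow monocytes. Points are libraries and bars are mean ± SD (n = 3); Slc16a3 has means of 3.91, 80.8 and 72.1, and Gstm1 has means of 579, 101 and 150.

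Among matrix proteases and remodelling enzymes 20 of 30 rose with TRMs, 2 fell and 8 did not pass, with 23 and 3 adjusted over the list alone (camera adjusted p = 6.68e-10; adjusted p = 0.0634 with an estimated correlation). The stromelysin Mmp10 rose 7.52-fold, the collagen lysyl hydroxylase Plod2 6.55-fold and the collagen prolyl hydroxylase P4ha1 4.6-fold. Among collagens, laminins and other matrix proteins 16 of 29 rose and 13 did not pass, with 19 adjusted over the list alone (camera adjusted p = 6.02e-10; adjusted p = 0.27 with an estimated correlation). Col6a1 rose 7.03-fold to 403 ± 127, Col6a2 6.65-fold and Col18a1 3.6-fold. Of 23 mesenchymal genes 11 rose and 12 did not pass, with 16 adjusted over the list alone (camera adjusted p = 4.58e-06; adjusted p = 0.242 with an estimated correlation). Vim, the intermediate filament vimentin, rose 4.24-fold, from 210 ± 71.7 to 868 ± 194, and the matrix protein Tnc rose 9.05-fold. Summed over the mesenchymal list, values were 8565, 9041 and 11710 CPM alone and 7070, 13500 and 12630 CPM with TRMs. The sum of TRM replicate 1 lay below the range alone. In the TGF-beta list 11 of 27 rose, 2 fell and 14 did not pass, with 12 and 3 adjusted over the list alone (camera adjusted p = 0.0448; adjusted p = 0.355 with an estimated correlation). Id3, a repressor of helix-loop-helix factors, rose 4.37-fold, and Tgfb1 rose 2.6-fold. Summed over the TGF-beta list, values were 27820, 28660 and 33910 CPM alone and 21140, 28770 and 27510 CPM with TRMs. The sums of TRM replicates 1 and 3 lay below the range alone. That list call was lost without alone replicate 2 (0.0537), TRM replicate 2 (0.0556) or 3 (0.0788), or monocyte replicate 1 (0.059) or 2 (0.0543), with the 1 CPM filter (0.0546) and with the GC and length trend removed (0.0944). With the replicate block the adjusted p was 0.0624, and without TRM replicate 2 the risen members numbered 7. The fallen TGF-beta members numbered 1 without any alone replicate or TRM replicate 1 or 2, and 4 without monocyte replicate 1; the fallen proteases numbered 1 without alone replicate 1 or 3 or TRM replicate 2 or 3.

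Of 36 G2/M and mitosis genes 33 rose with TRMs and 3 did not pass, with 34 adjusted over the list alone (camera adjusted p = 1.43e-21; adjusted p = 0.206 with an estimated correlation). The mitotic kinesin Kif20a rose 3.49-fold, the anaphase activator Cdc20 2.49-fold and the kinase Cdk1 2.43-fold. Of 33 G1/S and replication genes 18 rose, 1 fell and 14 did not pass, with 22 and 1 adjusted over the list alone (camera adjusted p = 4.94e-09; adjusted p = 0.0614 with an estimated correlation). Uhrf1, which maintains DNA methylation, rose 3.24-fold and the replicative helicase subunit Mcm5 2.15-fold. Without TRM replicate 2 the risen members of this list numbered 9, and the fallen call was lost without any alone or TRM replicate or monocyte replicate 2.

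In the NF-kappaB and inflammatory list 10 of 34 rose with TRMs, 1 fell and 23 did not pass, with 14 and 5 adjusted over the list alone (camera adjusted p = 0.00832; adjusted p = 0.561 with an estimated correlation). Il1a, which encodes interleukin-1 alpha, rose 5.39-fold, from 44.8 ± 2.96 to 241 ± 20.6, and the cytokine Csf2 rose 3.16-fold. The member that fell was Ccl20, a chemokine (2.43-fold lower); the fallen members numbered 3 without alone replicate 2, TRM replicate 1, or monocyte replicate 1 or 3, and 2 without monocyte replicate 2. Outside the lists, the matrix protein Ecm1 rose 8.34-fold, from 137 ± 18.6 to 1139 ± 157 (limma adjusted p = 7.16e-07). Among called genes whose groups did not overlap and whose mean was at least 5 in the higher group, the largest folds upward were those of genes at low levels: the tyrosine phosphatase Ptpn5 (59.7-fold), Arap3 (49.4-fold), the actin-bundling Espn (37.0-fold), the water channel Aqp8 (31.5-fold) and the chemokine receptor Ackr3 (26.6-fold).

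Lists that lay lower with TRMs had fewer called members. Of 28 epithelial identity genes 5 fell and 23 did not pass, with 3 adjusted over the list alone (camera adjusted p = 0.00808; adjusted p = 0.827 with an estimated correlation). The tight junction genes Ocln (2.37-fold lower) and Cgn (2.34-fold lower) fell. Cdh1, which encodes E-cadherin, was at 1650 ± 97.6 and 1397 ± 100.2 (limma adjusted p = 0.401). Summed over the list, values were 21110, 18530 and 20690 CPM alone and 23020, 18850 and 17690 CPM with TRMs. The sum of TRM replicate 1 lay above the range alone, that of replicate 2 within it and that of replicate 3 below it. The fallen members numbered 3 without alone replicate 1 or 3, TRM replicate 2 or 3, or monocyte replicate 2, and 8 without TRM replicate 1 or monocyte replicate 3; without TRM replicate 3 the list call was lost (0.101). In the NRF2 and antioxidant list 6 of 29 fell, 3 rose and 20 did not pass, with 8 and 3 adjusted over the list alone (camera adjusted p = 0.0364; adjusted p = 0.827 with an estimated correlation). Gclc, which makes the first step of glutathione synthesis, fell (2.35-fold lower), as did the catalase gene Cat (1.77-fold lower) and the transferase Gsta4. The call was lost without alone replicate 2 (0.345) or TRM replicate 3 (0.171), and 1 member rose without TRM replicate 2. Immediate early and heat shock genes, listed as a possible sign of how cells were dissociated, also lay lower. Whether dissociation moved them was not tested. Of 28 members 6 fell, 2 rose and 20 did not pass, with 8 fallen and 2 risen adjusted over the list alone. As a set the camera adjusted p was 0.0197, and 0.355 with an estimated correlation. Nr4a1 (2.82-fold lower) and Btg2 (2.03-fold lower) fell. Without TRM replicate 2, 3 members fell and 1 rose; 1 rose too without alone replicate 1 or 3, TRM replicate 3 or monocyte replicate 2.

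Further genes that fell with TRMs were Spry1, a brake on receptor tyrosine kinase signalling (492 ± 58.3 to 89.5 ± 27.3, 5.63-fold lower, limma adjusted p = 1.15e-05), the transcription factor Tfcp2l1 (4.67-fold lower), the receptor Paqr8 (4.13-fold lower) and the phosphatase Dusp16 (2.95-fold lower). Ugt2b34, a glucuronosyltransferase, fell from 32.8 ± 0.813 to 1.08 ± 0.817 (44.0-fold lower), Cyp2c65 fell 45.0-fold and the growth factor receptor Fgfr3 56.6-fold. Cyp2c55 had 426 reads over the libraries alone and 2 with TRMs, a ratio of 157 with a counting interval of 43.3 to 1300, and its call was lost without alone replicate 3 (0.0536).

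Lists without a set call in this comparison had adjusted p between 0.0596 and 0.907. Of 38 interferon genes 2 rose and 4 fell (4 fell adjusted over the list alone; adjusted p = 0.586), with Ifit1bl1 10.5-fold lower. Of 20 MHC class I genes 1 rose and 1 fell, the same counts as adjusted over the list alone (adjusted p = 0.632); H2-M3 rose 3.21-fold. Among oxidative phosphorylation genes 2 of 40 rose, and none adjusted over the list alone (adjusted p = 0.586). Cholesterol genes had 2 of 25 risen, 1 adjusted over the list alone (adjusted p = 0.0757), and fatty acid genes 2 of 25 risen and 3 fallen, as adjusted over the list alone (adjusted p = 0.328), with the desaturase Scd2 1.89-fold higher. In the unfolded protein list 1 of 29 rose and 4 fell, against 3 and 6 adjusted over the list alone (adjusted p = 0.0596), with Herpud1 2.19-fold lower. Of 19 p53 targets 2 rose and 4 fell, as adjusted over the list alone (adjusted p = 0.735). Of 17 alveolar epithelial genes 3 rose and 6 fell, against 5 and 8 adjusted over the list alone (adjusted p = 0.632); the surfactant gene Sftpd fell from 36.0 ± 12.4 to 5.65 ± 3.05 and the caveolin Cav1 rose 4.96-fold. This list had a median of 0.12 and a mean of -0.04 on the log2 scale. RAS-MAPK output genes had 2 of 24 risen and 4 fallen, against 4 and 5 adjusted over the list alone (adjusted p = 0.323), and WNT and Notch targets 4 of 15 risen and 3 fallen, as adjusted over the list alone (adjusted p = 0.586). Of 40 ribosomal protein genes 1 rose, also adjusted over the list alone (adjusted p = 0.907). The 8 mitochondrial genes held 0 calls in limma and edgeR, and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0922); without TRM replicate 1, 3 were lower. These small counts shifted with single libraries; the fallen alveolar epithelial genes numbered 3 without alone replicate 1 or 3, or TRM replicate 2 or 3.

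Across all genes limma called 2262 of 12326 with TRMs, 1257 higher and 1005 lower. The count was 1442 without alone replicate 1, 1391 without alone replicate 3 and 1217 without TRM replicate 2. Scaling by library totals, an alternative chosen after seeing the data, gave 1003 higher and 1302 lower. The authors' deposited table for this comparison called 2625 of 11085 genes, 1326 higher and 1299 lower, and 2104 of those were called here too. Its log2 fold changes correlated with these at 0.99 across genes, which are not independent replicates.

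The second comparison asked the same of bone-marrow monocytes. Kif20a was at 16.7 ± 4.47 (SD, n = 3) alone and 109 ± 2.67 (SD, n = 3) with monocytes, a 6.67-fold rise (log2 2.74, SE 0.21, limma adjusted p = 7.15e-06), and Cdc20 rose 4.76-fold, from 21.7 ± 3.86 to 103 ± 8.99 (SD, n = 3; limma adjusted p = 7.15e-06). Slc16a3 rose 17.8-fold, to 72.1 ± 25.8 (SD, n = 3; limma adjusted p = 4.95e-06). Dsg2, which encodes a desmosomal cadherin, fell from 198 ± 10.9 to 52.7 ± 4.45 (SD, n = 3; 3.77-fold lower, log2 -1.91, limma adjusted p = 4.95e-06).

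All 36 G2/M and mitosis genes rose with monocytes, as adjusted over the list alone (camera adjusted p = 4.48e-31; adjusted p = 0.127 with an estimated correlation). Cdk1 rose 3.77-fold to 102 ± 9.72, and Ube2c, a ubiquitin carrier of the anaphase complex, 4.25-fold. Of 33 G1/S and replication genes 28 rose and 5 did not pass, with 29 adjusted over the list alone (camera adjusted p = 7.13e-17). This call held with an estimated correlation (adjusted p = 0.0208). Mcm5 rose 3.76-fold, Uhrf1 5.13-fold and the replication factor Cdc45 3.83-fold.

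Glycolysis genes had 17 of 19 risen and 2 not passing, with 18 adjusted over the list alone (camera adjusted p = 4.65e-16; adjusted p = 0.136 with an estimated correlation). Ldha rose 4.23-fold to 2110 ± 287, Pfkl 3.45-fold and Pgam1 3.46-fold. In the hypoxia list 15 of 27 rose, 2 fell and 10 did not pass, with 16 and 2 adjusted over the list alone (camera adjusted p = 0.000132; adjusted p = 0.326 with an estimated correlation). Angptl4, a lipase inhibitor, rose 4.72-fold to 678 ± 142, Ak4 4.25-fold and Egln1 2.23-fold. Of 40 oxidative phosphorylation genes 10 rose and 30 did not pass, as adjusted over the list alone (camera adjusted p = 0.00472; adjusted p = 0.827 with an estimated correlation), with the cytochrome oxidase subunit Cox6a1 1.74-fold higher. The risen members numbered 2 without alone replicate 1, 4 without alone replicate 3, 6 without monocyte replicate 2 and 5 without monocyte replicate 3. The list call was lost without monocyte replicate 3 (0.314) and with the GC and length trend removed (0.0609). In the same libraries Mrc1 rose 7.57-fold to 39.2 ± 7.49 and F13a1 13.4-fold to 13.4 ± 5.38.

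Among matrix proteases and remodelling enzymes 20 of 30 rose with monocytes, 3 fell and 7 did not pass, as adjusted over the list alone (camera adjusted p = 3.89e-07; adjusted p = 0.0982 with an estimated correlation). The stromelysin Mmp3 rose 25.8-fold, from 31.1 ± 31.4 to 607 ± 216, Mmp10 5.3-fold and the inhibitor Timp1 4.7-fold. Mmp12, a macrophage elastase, rose 31.3-fold from a low level, to 6.56 ± 1.67. Of 29 collagens, laminins and other matrix proteins 15 rose and 14 did not pass, with 16 risen and 2 fallen adjusted over the list alone (camera adjusted p = 2.86e-06; adjusted p = 0.411 with an estimated correlation). Col6a1 rose 11.5-fold to 673 ± 249 and Col6a2 9.76-fold. Of 23 mesenchymal genes 11 rose, 1 fell and 11 did not pass, with 14 and 1 adjusted over the list alone (camera adjusted p = 4.78e-05; adjusted p = 0.28 with an estimated correlation). Vim rose 6.1-fold to 1248 ± 277, and the integrin Itga5 5.55-fold. Summed over the mesenchymal list, values were 8565, 9041 and 11710 CPM alone and 8476, 9843 and 9207 CPM with monocytes. No monocyte sum lay above the range alone. The fallen mesenchymal call was lost without any alone replicate or monocyte replicate 1, and 1 collagen or matrix gene fell without TRM replicate 1 or monocyte replicate 2.

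Of 28 epithelial identity genes 18 fell with monocytes and 10 did not pass, with 20 adjusted over the list alone (camera adjusted p = 1.25e-09; adjusted p = 0.489 with an estimated correlation). Ocln (3.93-fold lower), Cgn (2.61-fold lower), the desmoplakin gene Dsp (2.58-fold lower) and Cdh1 fell, the last from 1650 ± 97.6 to 869 ± 259 (limma adjusted p = 0.00173). Summed over the list, values were 21110, 18530 and 20690 CPM alone and 12570, 13400 and 19160 CPM with monocytes, so the sum of monocyte replicate 3 lay within the range alone. Immediate early and heat shock genes, listed as a possible sign of dissociation, lay lower as well. Of 28 members 11 fell and 17 did not pass, with 12 fallen adjusted over the list alone. As a set the camera adjusted p was 0.000291, and 0.198 with an estimated correlation. Nr4a1 (2.76-fold lower), Jun (2.22-fold lower) and Btg2 (2.45-fold lower) fell. The fallen members numbered 7 without alone replicate 1 and 6 without alone replicate 3, and 1 rose without alone replicate 2 or monocyte replicate 1.

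Beyond the lists, Gstm1 fell from 579 ± 53.3 to 150 ± 38.3 (3.92-fold lower, limma adjusted p = 2.79e-05), Ugt2b34 21.2-fold, Cyp2c65 28.5-fold and Tfcp2l1 5.78-fold. Akap13, an A-kinase anchoring protein, fell (2.65-fold lower), as did Mtss1, an actin regulator (3.12-fold lower), Spry1 (4.24-fold lower) and Akap12, from 6.26 ± 2.61 to 0.623 ± 0.896. Add2, an adducin of the membrane skeleton, rose 5.43-fold, Ecm1 3.85-fold and Arap3 79.2-fold from a low level.

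Lists without a set call with monocytes had adjusted p between 0.0657 and 0.928. TGF-beta genes had 10 of 27 risen and 5 fallen, against 11 and 5 adjusted over the list alone (adjusted p = 0.263); Id3 rose 6.06-fold and Ccn2 fell from 2196 ± 52.7 to 860.0 ± 291, and the risen members numbered 6 without alone replicate 1 or monocyte replicate 1. Of 38 interferon genes 5 rose and 4 fell, against 5 and 3 adjusted over the list alone (adjusted p = 0.285), with Bst2 2.28-fold higher. MHC class I genes had 2 of 20 risen and 1 fallen, against 1 risen adjusted over the list alone (adjusted p = 0.76, median 0.09 and mean -0.00287 on the log2 scale). In the NF-kappaB list 6 of 34 rose and 6 fell, against 7 and 6 adjusted over the list alone (adjusted p = 0.842); Il1a rose 2.16-fold and the chemokine Cxcl5 fell 2.83-fold. Cholesterol genes had 2 of 25 risen, as adjusted over the list alone (adjusted p = 0.12). Fatty acid genes had 3 of 25 risen and 4 fallen, against 3 and 5 adjusted over the list alone (adjusted p = 0.76, median 0.000576 and mean -0.08 on the log2 scale). In the unfolded protein list 2 of 29 rose and 7 fell, against 2 and 8 adjusted over the list alone (adjusted p = 0.12), and in the NRF2 list 4 of 29 rose and 9 fell, as adjusted over the list alone (adjusted p = 0.0989), with Gclc 2.46-fold lower. Of 19 p53 targets 2 rose and 4 fell, as adjusted over the list alone (adjusted p = 0.317). Alveolar epithelial genes had 6 of 17 risen and 6 fallen, against 6 and 7 adjusted over the list alone (adjusted p = 0.795); Aqp5 rose 2.26-fold and Sftpd fell 7.92-fold. RAS-MAPK genes had 4 of 24 risen and 4 fallen, against 5 and 4 adjusted over the list alone (adjusted p = 0.586). WNT and Notch targets had 4 of 15 risen and 5 fallen, as adjusted over the list alone (adjusted p = 0.902, median -0.03 and mean 0.18 on the log2 scale). Ribosomal protein genes had 4 of 40 risen, 2 adjusted over the list alone (adjusted p = 0.0922). The 8 mitochondrial genes held 0 calls in limma and edgeR, with 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0657); 1 was lower without TRM replicate 1 and 3 without monocyte replicate 3. Small counts shifted with single libraries here too; the risen unfolded protein genes numbered 8 without alone replicate 2.

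Across all genes limma called 3366 with monocytes, 1806 higher and 1560 lower. Scaling by library totals, chosen after seeing the data, gave 1603 higher and 1758 lower, so which direction holds more genes depends on the scaling. The count was 2240 without alone replicate 3. The authors' deposited table called 3123 of 11081 genes, 1597 higher and 1526 lower, with 2947 called here too and log2 fold changes correlated at 0.986 across genes.

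A further question was whether the co-cultures moved the same genes. Called in both with the same direction were 1839 genes, 999 higher and 840 lower, among them Slc16a3, Ldha, Ecm1, Vim, Col6a1 and Kif20a on the higher side and Gstm1, Spry1, Tfcp2l1, Ocln and Ugt2b34 on the lower. Scaling by library totals gave 816 higher and 1030 lower among 1846 shared genes. With the TMM scaling the shared genes were 81.3% of the calls with TRMs and 54.6% of those with monocytes. The log2 fold changes correlated at r = 0.792 across genes, which are not independent replicates. The simulations with shared controls gave a mean r of 0.497 and a highest of 0.531. The covariance was 0.638 against a simulated mean of 0.106, a difference of 0.532. The 3 control libraries were not split between the co-cultures, and the reach of control deviations shared by many genes was not tested. Part of the excess over the simulated mean may therefore still come from the shared controls. Genes called in both numbered 1155 without alone replicate 1, 1125 without alone replicate 3 and 1044 without TRM replicate 2.

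**Figure D2:**
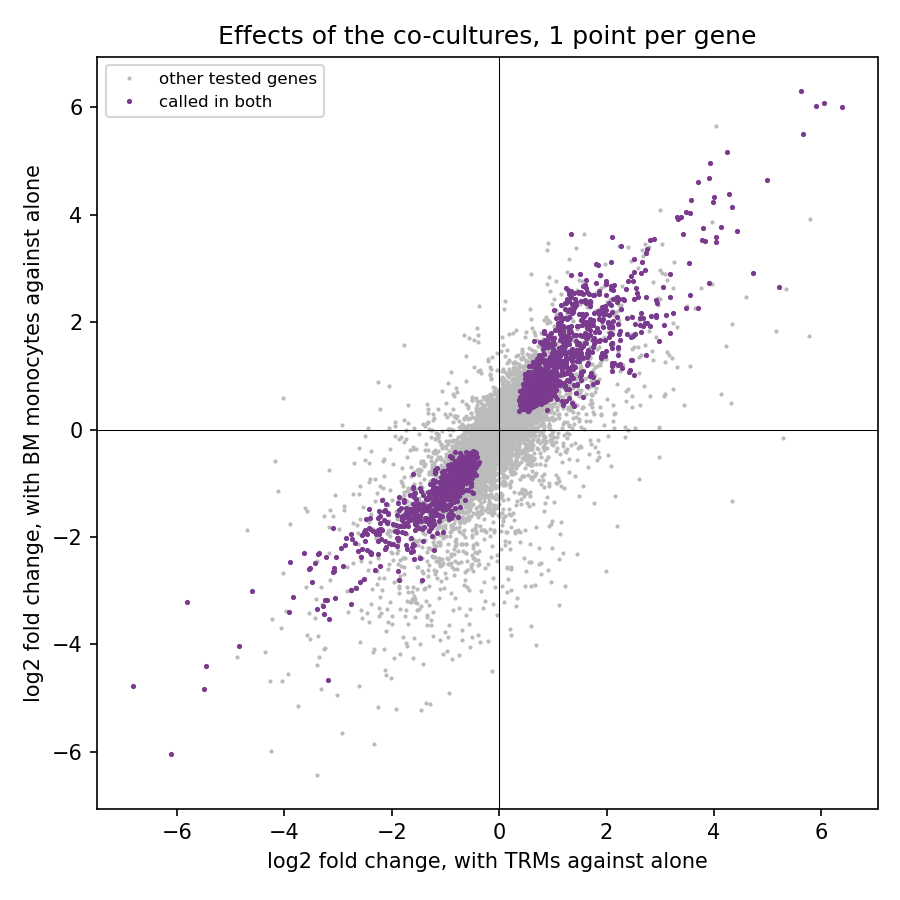
Each point is 1 of the 12326 genes tested, with its log2 fold change of TRM co-culture against alone on the x axis and of monocyte co-culture against alone on the y axis. The points rise along the diagonal (r = 0.792 across genes).

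The third comparison set the co-cultures against each other. Pfkp, of the glycolysis list, was at 208 ± 49.96 (SD, n = 3) with TRMs and 75.2 ± 4.33 (SD, n = 3) with monocytes (2.71-fold, log2 1.44, SE 0.18, limma adjusted p = 0.00573), and Egln1, of the hypoxia list, at 455 ± 32.5 and 209 ± 27.7 (SD, n = 3; 2.19-fold, limma adjusted p = 0.00573). Il1a was 2.5-fold higher with TRMs, at 241 ± 20.6 against 97.6 ± 18.1 (SD, n = 3; limma adjusted p = 0.00573). Sod3, the extracellular superoxide dismutase, was lower with TRMs, at 13.1 ± 3.2 against 64.1 ± 15.5 (SD, n = 3; 4.91-fold, log2 -2.30, limma adjusted p = 0.00846). The calls of Pfkp, Egln1 and Il1a were lost without TRM replicate 2 (0.0509 each), and that of Sod3 without TRM replicate 2 (0.0509) or 3 (0.0507) or monocyte replicate 2 (0.0645).

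In the hypoxia list 7 of 27 genes were higher with TRMs and 20 did not pass, with 18 adjusted over the list alone (camera adjusted p = 3.16e-21; adjusted p = 0.0614 with an estimated correlation). Ero1l, an oxidase of disulfide formation, was at 352 ± 111 against 95.3 ± 12.1 (3.57-fold, limma adjusted p = 0.00816; lost without TRM replicate 2, 0.0797, or 3, 0.0507). Vegfa, the vascular growth factor, was at 702 ± 58.5 against 261 ± 33.1 (2.7-fold, limma adjusted p = 0.0148). The Vegfa call was lost without TRM replicate 1 (0.0678), 2 (0.0872) or 3 (0.0507) or monocyte replicate 1 (0.0516) or 2 (0.0645). The higher members numbered 2 without TRM replicate 1, 0 without TRM replicate 2, 1 without TRM replicate 3, and 2 without monocyte replicate 1 or 2; limma gave 19 at an unadjusted p under 0.05 and edgeR 7 with all libraries. Of 19 glycolysis genes 1 was higher, Pfkp, and 18 did not pass, with 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.73e-10; adjusted p = 0.242 with an estimated correlation). Without monocyte replicate 3, 2 glycolysis genes were higher. Gapdh was at 2106 ± 243 and 1417 ± 152 (limma adjusted p = 0.135).

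Of 36 mitosis genes 3 were lower with TRMs than with monocytes and 33 did not pass, with 34 adjusted over the list alone (camera adjusted p = 1.13e-33; adjusted p = 0.117 with an estimated correlation). The kinesin Kif11 was at 37.5 ± 3.71 against 74.9 ± 7.96 (limma adjusted p = 0.0241) and Cdc20 at 53.9 ± 9.05 against 103 ± 8.99 (limma adjusted p = 0.0363). The lower members numbered 1 without alone replicate 1 or 3, 13 without alone replicate 2 and 6 without monocyte replicate 3. Without any other library 0 passed in limma, against 34 at an unadjusted p under 0.05 and 3 in edgeR with all libraries. The Kif11 call was lost without those 5 libraries (adjusted p up to 0.106) and that of Cdc20 without them or alone replicate 1 or 3 (up to 0.158). G1/S genes held 0 calls in limma and edgeR, with 19 of 33 lower at an unadjusted p under 0.05 and 15 lower adjusted over the list alone. The list as a set was lower with TRMs (camera adjusted p = 1.55e-17), a call that held with an estimated correlation (adjusted p = 0.0208). Mcm5 was at 93.2 ± 20.2 and 161 ± 11.6 (limma adjusted p = 0.0613), and 2 members were lower without alone replicate 2.

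Epithelial identity genes were higher with TRMs as a set (camera adjusted p = 7.82e-14; adjusted p = 0.355 with an estimated correlation). In limma and edgeR 0 of 28 were called, 14 were higher at an unadjusted p under 0.05, and 13 adjusted over the list alone. Without monocyte replicate 3, 11 were called higher. Cdh1 was at 1397 ± 100.2 and 869 ± 259 (limma adjusted p = 0.107). In the NF-kappaB list 2 of 34 were higher with TRMs and 32 did not pass, with 3 adjusted over the list alone (camera adjusted p = 2.61e-06; adjusted p = 0.242 with an estimated correlation). These were Il1a and Csf3, a granulocyte growth factor, at 32.8 ± 3.06 against 14.0 ± 2.62 (limma adjusted p = 0.0272). The Csf3 call was lost without TRM replicate 1 (0.117), 2 (0.131) or 3 (0.0779) or monocyte replicate 2 (0.112); 1 member passed without TRM replicate 1 or monocyte replicate 2, and 0 without TRM replicate 2, against 11 at an unadjusted p under 0.05 with all libraries. Interferon genes lay lower with TRMs (camera adjusted p = 0.000373; adjusted p = 0.489 with an estimated correlation), with 0 of 38 called in limma and edgeR and adjusted over the list alone, and 9 lower at an unadjusted p under 0.05.

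Oxidative phosphorylation genes (camera adjusted p = 2.8e-05; adjusted p = 0.728 with an estimated correlation) and ribosomal protein genes (camera adjusted p = 0.00158; adjusted p = 0.827 with an estimated correlation) lay lower with TRMs. Neither held a call in limma or edgeR, over all genes or adjusted over the list alone, and 6 and 2 members were lower at an unadjusted p under 0.05. Without monocyte replicate 3 the first call was lost (0.315) and the second list turned direction (0.622); with the GC and length trend removed the second was lost (0.0557). Immediate early genes lay higher with TRMs (camera adjusted p = 0.00279; adjusted p = 0.254 with an estimated correlation), with 0 of 28 called in limma and edgeR, 6 higher at an unadjusted p under 0.05 and 1 adjusted over the list alone.

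Lists without a set call between the co-cultures had adjusted p between 0.12 and 0.939. Of 29 collagens, laminins and other matrix proteins 2 were higher, among them Lama3 (2.72-fold, limma adjusted p = 0.0363), against 4 higher and 3 lower adjusted over the list alone (adjusted p = 0.586); edgeR called 0 of the 29, and limma gave 5 higher and 5 lower at an unadjusted p under 0.05. The Lama3 call was lost without alone replicate 1, any TRM replicate, or monocyte replicate 1 or 2 (adjusted p up to 0.167), in edgeR (0.0502) and with the GC and length trend removed (0.0834). Of 30 matrix proteases and remodelling enzymes 1 was higher, the prolyl hydroxylase P4ha2 (1.94-fold, limma adjusted p = 0.021), against 2 higher and 2 lower adjusted over the list alone (adjusted p = 0.323, median 0.05 and mean -0.00366 on the log2 scale). It was lost without any TRM replicate or monocyte replicate 1 or 2 (up to 0.116). Of 29 unfolded protein genes 1 was higher, the lipoprotein receptor Vldlr (2.28-fold, limma adjusted p = 0.0241), also adjusted over the list alone (adjusted p = 0.939, median -0.07 and mean 0.00871 on the log2 scale). The Vldlr call was lost without the same 5 libraries (up to 0.131). In limma and edgeR no member was called of the mesenchymal (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.686), MHC class I (2 and 1; adjusted p = 0.928, median -0.06 and mean 0.19 on the log2 scale), alveolar epithelial (1 lower; adjusted p = 0.586) and WNT and Notch lists (1 higher; adjusted p = 0.381). At an unadjusted p under 0.05 these lists had 1 higher and 2 lower, 2 and 1, 0 and 1, and 3 and 0. The TGF-beta (adjusted p = 0.262), cholesterol (0.928), fatty acid (0.395), NRF2 (0.632), p53 (0.193), RAS-MAPK (0.597) and mitochondrial lists (0.586) also held none, nor adjusted over the list alone, with 3 higher and 1 lower, 1 and 1, 2 and 5, 1 and 3, 2 and 1, 1 and 2, and 0 and 0 at an unadjusted p under 0.05.

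Across all genes limma called 49 between the co-cultures, 40 higher and 9 lower with TRMs. Ptgs1, a cyclooxygenase, was at 34.8 ± 7.79 with TRMs and 112 ± 29.1 with monocytes (3.18-fold lower, limma adjusted p = 0.0148). Its call was lost without TRM replicate 1 (0.0775) or 2 (0.0872) or monocyte replicate 1 (0.0557) or 2 (0.0694). The count was 27, 97 and 26 without alone replicates 1, 2 and 3, 7, 0 and 6 without TRM replicates 1, 2 and 3, and 13, 7 and 134 without monocyte replicates 1, 2 and 3. The 0 came from limma, with 1174 genes at an unadjusted p under 0.05; with all libraries limma gave 1437 at that level, edgeR called 44, limma-voom 86 and DESeq2 336. Scaling by library totals, chosen after seeing the data, gave 35 higher and 16 lower. Of the 49 genes 23 were called in both co-cultures against alone, 24 in 1 of them and 2 in neither.

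**Figure D3:**
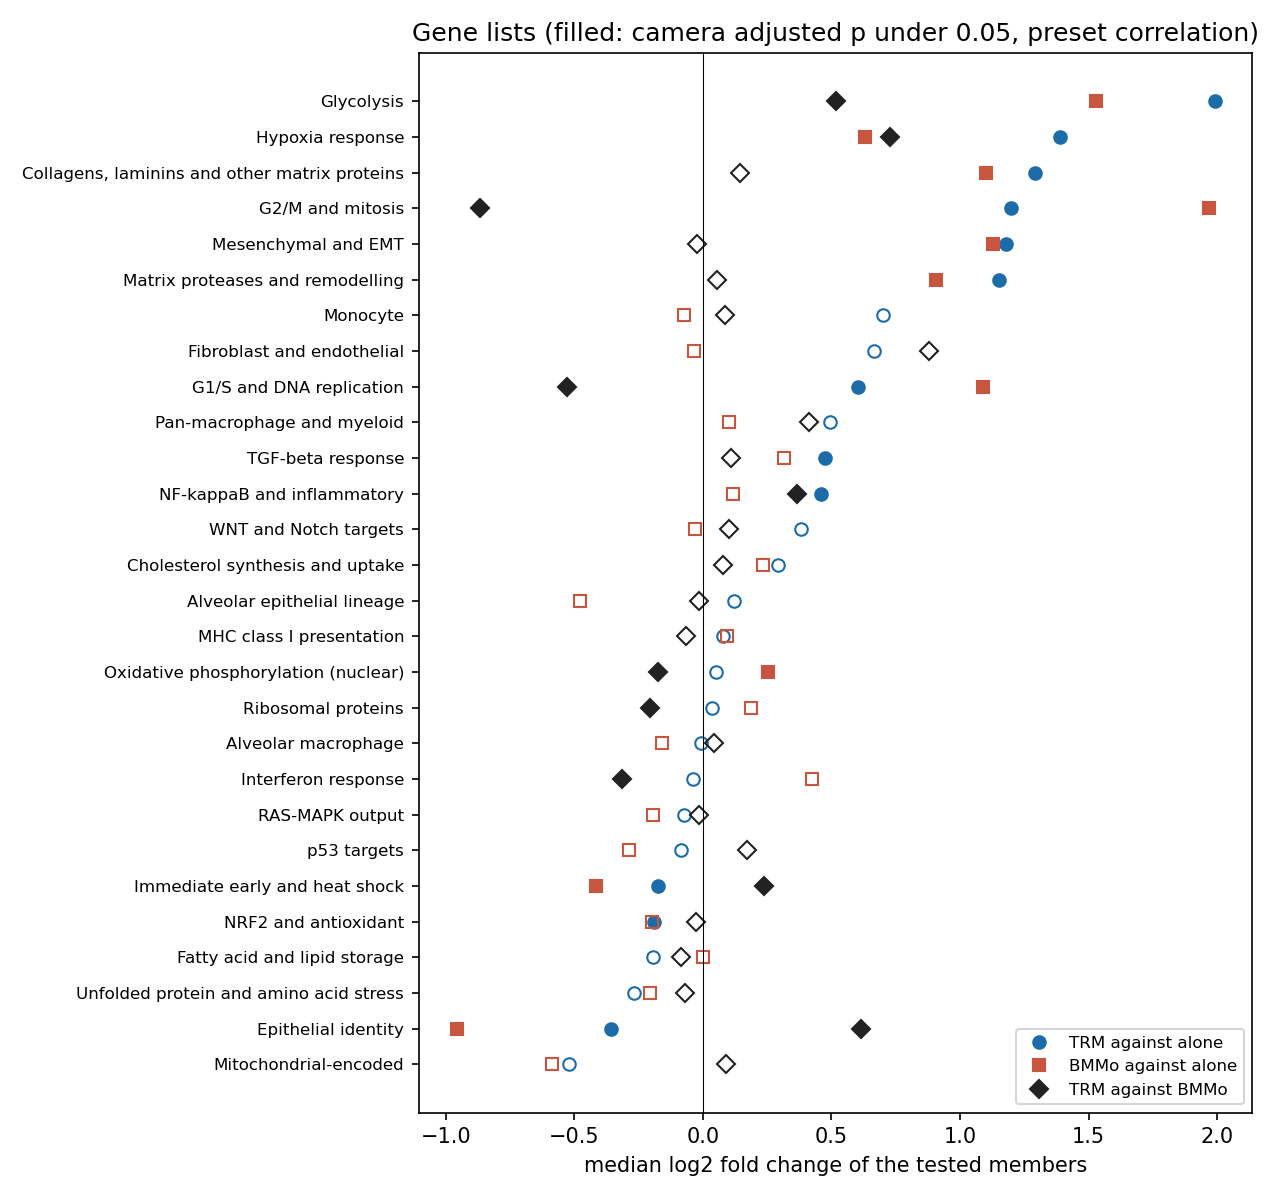
Median log2 fold change of the tested members of each of the 28 gene lists in the 3 contrasts. Filled symbols have a camera adjusted p under 0.05 with the preset correlation, which most lists lost with an estimated correlation; the mitosis list has medians of 1.20 and 1.97 against alone and -0.87 between the co-cultures.

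Markers of other cell types were tested as lists too. Of 23 pan-macrophage genes 2 rose with TRMs, Mrc1 and Cd53 (2.45-fold), as adjusted over the list alone (camera adjusted p = 0.323). With monocytes 2 rose, Mrc1 and Gpnmb (7.46-fold, to 10.1 ± 1.38), and 1 fell, Ptprc, against 2 risen adjusted over the list alone (adjusted p = 0.786, median 0.10 and mean -0.01 on the log2 scale). Csf1r, the macrophage growth factor receptor, was at 3.02 ± 0.764, 5.91 ± 0.725 and 3.38 ± 0.375 (limma adjusted p = 0.0613 and 0.726 against alone). Alveolar macrophage markers had 3 of 16 risen and 1 fallen with TRMs, as adjusted over the list alone (adjusted p = 0.589, median -0.01 and mean 0.05 on the log2 scale), and 3 risen and 3 fallen with monocytes, against 3 and 4 adjusted over the list alone (adjusted p = 0.85). Krt79 rose 3.34-fold and Plet1 fell 1.92-fold with TRMs. Monocyte markers had 2 of 15 risen and 2 fallen with TRMs, against 4 and 2 adjusted over the list alone (adjusted p = 0.586), and 2 risen and 3 fallen with monocytes, as adjusted over the list alone (adjusted p = 0.928, median -0.08 and mean 0.12 on the log2 scale). F13a1 and Ly6c1 (13.5 ± 2.87, 73.1 ± 7.68 and 35.2 ± 17.5) rose in both, and Nr4a1, also an immediate early gene, fell in both. Of 6 fibroblast and endothelial markers 1 rose in each co-culture, Gsn (2.03-fold and 1.91-fold), also adjusted over the list alone (adjusted p = 0.285 and 0.76); with monocytes the median was -0.03 and camera's direction up. Between the co-cultures the pan-macrophage (adjusted p = 0.323), alveolar macrophage (0.149), monocyte (0.12) and fibroblast lists (0.223) held 0 calls in limma and edgeR, with 2 higher and 1 lower, 4 and 0, 1 and 0, and 0 and 0 at an unadjusted p under 0.05. Adjusted over the list alone, 1 pan-macrophage gene was lower and 1 monocyte gene higher.

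The neutrophil list had 3 tested members of 20, too few for a list test. Mmp9 rose in both co-cultures, from 0.39 ± 0.403 to 5.37 ± 1.4 with TRMs and 15.3 ± 16.9 with monocytes (limma adjusted p = 0.00237 and 0.00043), and both calls were lost in limma-voom (0.168 and 0.0748). Lcn2 (29.2 ± 6.86, 53.2 ± 22.7 and 20.2 ± 2.36) and Ltf (4.6 ± 3.19, 8.7 ± 5.97 and 2.85 ± 1.89) did not pass. The lymphocyte list had 1 tested member of 21, Ms4a1, at 0.84 ± 0.927, 0.36 ± 0.53 and 0.403 ± 0.524. The erythroid list had 2 of 10, Klf1 at 0.863 ± 0.431, 0.679 ± 0.327 and 0.836 ± 0.549 and the carbonic anhydrase Car2 at 241 ± 73.6, 236 ± 47.7 and 171 ± 95.1, none of which passed.

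In GRCm38 (mm10) coordinates, Slc16a3 lies on chromosome 11 from 120948480 to 120960868, Ldha on chromosome 7 from 46841475 to 46855627, and Pfkp on chromosome 13 from 6579768 to 6648777. Egln1 spans chromosome 8 from 124908587 to 124949324 and Ecm1 chromosome 3 from 95734147 to 95739569. Il1a lies on chromosome 2 from 129299610 to 129309972, Gstm1 on chromosome 3 from 108012255 to 108017973 and Ugt2b34 on chromosome 5 from 86889767 to 86906937. Kif20a spans chromosome 18 from 34624613 to 34633277, Cdc20 chromosome 4 from 118432901 to 118437352, Dsg2 chromosome 18 from 20558074 to 20604521 and Sod3 chromosome 5 from 52363791 to 52371418. All are annotated protein-coding genes, and values are summed over the gene. Members of multigene families may share reads with close copies and are uncertain, among them Gstm1, Gsta4, Ugt2b34, Cyp2c55, Cyp2c65, Mmp3, Mmp10, Ifit1bl1, H2-M3, Ly6c1 and the ribosomal protein genes. Also uncertain are genes that share exon sequence with a gene on the opposite strand, among them Kif20a (with Cdc23), Cdc20 (with Elovl1), Pfkp (with Pitrm1), Il1a, Add2, Bnip3, Ccn2, Cdc45, Plet1, Plod2, Tnc, Spry1, Fgfr3, Dsg2, Dsp, Ube2c (with Tnnc2), Mmp12 (with Mmp1b), Csf2, Ptgs1, Lama3, Jun, F13a1, Gapdh (with Iffo1) and Csf1r; Ecm1, Arap3, Scd2 and Tfcp2l1 overlap another annotated gene on their own strand.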

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

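Chosen only after their results were seen were the tests of single libraries, of carried-over macrophage RNA and of carried-over bone-marrow RNA; scaling by library totals was added after seeing the data, beside scalings that were planned.

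The 36 mitosis genes had a median log2 change of -0.868 for TRM against monocyte co-culture (camera adjusted p = 1.13e-33; adjusted p = 0.117 with an estimated correlation). The list stood out because the direct contrast was called as a set, but only 3 of its genes passed in limma, and none when any TRM replicate or monocyte replicate 1 or 2 was left out. A single library as the source of the median was argued against, since the value nearest to 0 was -0.787 over the 6 left-out co-culture libraries. Over 3 other scalings the value nearest to 0 was -0.856, so the choice among these scalings did not make the median. TMM factors lay between 0.948 and 1.049, so these scalings could move it little. An error that all of them share was not tested. The summed level of 40 myeloid markers, monocyte minus TRM co-culture, was -1670 CPM, but 93.5% of the sum in tumour cells alone came from Fn1, Nr4a1, Klf2 and Cd14, so this sum cannot tell whether cycling bone-marrow cells were carried through the GFP gate. A further sum took the 28 markers with a mean under 5 CPM in tumour cells alone. It was 46.1 ± 5.02 alone, 82.0 ± 22.2 with TRMs and 75.7 ± 20.2 with monocytes (SD, n = 3). The rise with monocytes was 29.5, beside a difference of 1170 between the co-cultures for the mitosis genes. Mrc1, which rose in both co-cultures, lay above that limit and is not in this sum. Cycling precursors may also hold few of these markers. Such cells therefore stay open beside the hypothesis that tumour cells divided more with monocytes.

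The median log2 change between the co-cultures was 0.519 for the glycolysis list and 0.726 for the hypoxia list, where 1 of 19 and 7 of 27 genes passed in limma and the set calls were lost with an estimated correlation (adjusted p = 0.242 and 0.0614). Against alone the set calls were lost in the same way, with adjusted p = 0.0817 and 0.0634 with TRMs and 0.136 and 0.326 with monocytes, although 17 and 21 members rose with TRMs and 17 and 15 with monocytes. The smallest of these medians against alone was 0.581 over 3 other scalings, so the choice among these scalings did not make the rises. These scalings could move the medians little, and an error that all of them share was not tested. With falls counted as 0, pan-macrophage genes rose by 103, 67.1 and 61.6 CPM in sum (TRMs against alone, monocytes against alone, between the co-cultures). Glycolysis genes rose by 13500, 10300 and 3150 CPM and hypoxia genes by 3270, 1230 and 2040 CPM, so the share was at most 5.46%. This argues against carried-over macrophage RNA as the whole cause if such cells hold more RNA of these markers than of the lists. That was not measured. The 40 myeloid markers together changed by 1150, -522 and 1670 CPM, or 8.52%, -5.07% and 53% of the glycolysis rises. Their sum in tumour cells alone came mostly from Fn1, Nr4a1, Klf2 and Cd14, so it cannot tell. A response of the tumour cells to less oxygen or more sugar use in larger spheroids may be considered, but spheroid size and oxygen were not analysed here and the biological explanation stays open.

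Further lists had co-culture effects that differed in the direct contrast, given as the median log2 change of TRM against monocyte co-culture. Epithelial identity genes had 0.615, NF-kappaB genes 0.365 and immediate early genes 0.236. G1/S genes had -0.529, interferon genes -0.316, ribosomal protein genes -0.207 and oxidative phosphorylation genes -0.176. Of these calls only that of the G1/S list held with an estimated correlation (adjusted p = 0.0208).

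Single genes stood out because their changes against alone had opposite signs and the direct contrast was called. With all libraries 0 genes were called against alone in both co-cultures with opposite signs. For no gene below did both changes against alone pass, so opposite responses are not shown. Egfr had a direct log2 difference of 1.58 (0.41 with TRMs and -1.17 with monocytes, limma adjusted p = 0.0283), lost without alone replicate 3, any TRM replicate, or monocyte replicate 1 or 2 (up to 0.16), and in a fit of only the groups compared (0.0504). Vegfa had 1.43 (1.19 and -0.24, limma adjusted p = 0.0148; lost without any TRM replicate or monocyte replicate 1 or 2, up to 0.0872). Csf3 had 1.25 (0.59 and -0.66, limma adjusted p = 0.0272; lost without any TRM replicate or monocyte replicate 2, up to 0.131). Vldlr had 1.19 (0.98 and -0.21, limma adjusted p = 0.0241; lost without any TRM replicate or monocyte replicate 1 or 2, up to 0.131).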

How the results depend on the processing

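Chosen only after the data were seen were edgeR on the recovered reads, log2(value + 1), library totals and the GC and length trend. The counts of called genes, the genes called in both co-cultures and their correlation kept their size (counts within 1.5 times) under each alternative, with these exceptions, whose cause was not tested unless said. Between the co-cultures 49 genes became 336 with DESeq2, 86 with limma-voom, 79 with the replicate block, 75 with log2(value + 1) and 81 with the trend removed. edgeR called 2183, 3255 and 44 genes in the 3 contrasts. A 2-fold minimum, which by construction keeps fewer genes, left 953, 1435 and 29 genes and 732 called in both. The correlation of the co-culture effects was 0.861 with log2(value + 1). Leaving out 1 library, which leaves a group with 2, gave 1217 to 2594 genes with TRMs, 2240 to 3530 with monocytes, 0 to 134 between the co-cultures (the 0 from limma without TRM replicate 2, with 1174 at an unadjusted p under 0.05), 1044 to 2021 called in both, and correlations of 0.7303 to 0.8228. Of the 12, 10 and 10 lists called, 0, 1 and 1 were called with an estimated correlation (6, 5 and 5 at an unadjusted p under 0.05), and fry called 10, 9 and 4; the G1/S list held for monocyte co-culture against alone and between the co-cultures. Leaving out 1 library gave 9 to 15, 10 to 14 and 10 to 14 lists. With BMMo for the monocyte co-culture, the list Ribosomal proteins, TRM against BMMo, turned direction without monocyte replicate 3 (adjusted p = 0.622) and had an adjusted p of 2.19e-14 without monocyte replicate 1. Of the 32 list calls 32 remained with RLE factors and with library totals, 31 with the replicate block and 29 with the trend removed. No named gene turned direction past the threshold under any alternative. With DESeq2, 5 of the 129 named genes it gave a p for with TRMs became called and none was lost; between the co-cultures 30 of 120 became called. These totals include named genes that were not called with all libraries. Without TRM replicate 2, 12 of 131 named genes lost their call with TRMs. Between the co-cultures 18 of 121 did, and since 0 of all genes stayed called, every named gene called there was lost. The replicate numbers were not taken to pair the libraries, because the labels do not say that libraries of the same number were made together. Of 9 pairs of the same number 5 had correlated deviations above 0.1 (-0.0246 to 0.429). A library correlated best with its own number in 12 of 18 comparisons, more than unlinked numbers would give on average. These values lean towards a link between libraries of the same number, which the main test leaves out. With the replicate block the calls were 2392, 3511 and 79. In simulated data, with 100 genes changed 2-fold and 100 changed 4-fold, 53% to 62% of 2-fold changes were called. Changes of that size may thus stay uncalled. The adjusted threshold depends on how many genes change, so these shares may differ in the real contrasts.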

Other observations

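Chosen only after their results were seen were the test of cell number and the test of liver and gut genes, and the removal of the GC and length trend was added after seeing the data.

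Several genes typical of liver and gut epithelium were lower in both co-cultures; those named here were chosen after their values were seen. Selenop, a plasma selenium carrier, was at 68.2 ± 2.54 alone, 4.84 ± 2.06 with TRMs and 14.3 ± 10.3 with monocytes (SD, n = 3; limma adjusted p = 3.42e-05 and 0.000553 against alone). Hhex, a homeobox factor of foregut development, was at 27.2 ± 10.5, 2.54 ± 1.75 and 4.52 ± 2.06, and the aldo-keto reductase Akr1c19 at 65.7 ± 5.56, 8.11 ± 2.75 and 13.4 ± 11.3. Pigr, which carries antibodies across epithelia, was at 40.8 ± 21.1, 5.84 ± 3.01 and 4.44 ± 3.0, and the gut lectin Lgals4 at 44.3 ± 6.06, 14.0 ± 5.17 and 14.1 ± 6.53. The trefoil peptide Tff2 was at 10.99 ± 0.642, 1.63 ± 1.39 and 1.88 ± 0.529, and the cytochrome gene Cyp3a13 at 110 ± 18.4, 37.9 ± 12.2 and 32.6 ± 7.52; all of these fell in both co-cultures in limma. Others did not pass, among them genes whose means were above those alone with TRMs: Ctse, a gastric protease, was at 445 ± 39.5, 574 ± 107 and 382 ± 82.5 (limma adjusted p = 0.187 and 0.34), and the intestinal cadherin Cdh17 at 206 ± 8.79, 290 ± 38.2 and 199 ± 89.8 (limma adjusted p = 0.179 and 0.687).

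A list of 71 such genes was written after some of their values had been seen, and 49 members were neither among those, nor genes named by rule, nor members of the lists tested earlier. Of the 24 of these that were tested 10 fell with TRMs and 11 with monocytes, and 14 and 13 did not pass, with median log2 changes of -1.13 and -1.47. The larger of the camera p-values was 3.24e-05 (with TRMs; 6.62e-06 with monocytes), and with an estimated correlation they were 0.125 and 0.102, so the set call is lost. A falling liver and gut epithelial programme in tumour cells may be a hypothesis, found and tested on the same data.

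Both co-cultures moved many genes the same way. Noise of the shared controls was argued against as the whole cause, since the covariance of the log2 fold changes was 0.638 and the highest of 50 simulations 0.118. How far control deviations shared by many genes could widen the simulated range was not tested. A bias with GC content and transcript length was argued against as the whole cause as well, since 1343 of the 1839 shared calls remained with the trend removed. The number of cells seeded cannot be told apart from the presence of TRMs or monocytes, because both co-cultures added 5000 cells. No spheroid of tumour cells alone began with as many cells as the co-cultures. A response common to both kinds of added cell stays open as a hypothesis.

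Regrouping the 6 libraries of a contrast gives 10 splits, too few for a share under 0.05 (the smallest is 0.1). In 1 of the 10 splits, the real 1, as many genes were called in each contrast. The real splits called 2262, 3366 and 49 genes, and the highest of the other splits called 0 in limma for each contrast, with 961, 1282 and 1243 genes at an unadjusted p under 0.05 against 3844, 4719 and 1437 in the real splits.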
